A study of Mus musculus with 12 samples.

How the data were processed

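The deposited table holds RNA sequencing of MC3T3-E1 subclone 14, a mouse pre-osteoblast cell line, grown in osteogenic medium for 5 days in 4 arms of 3 independent biological replicates, which makes 12 libraries. Per the labels' protocols, the arms received vehicle (Control), recombinant R-spondin 2 at 200 ng/ml (RSPO2), recombinant bone morphogenetic protein 2 at 100 ng/ml (BMP2) or both proteins (BMP2+RSPO2). The medium held 10% serum, 1% antibiotic, β-glycerophosphate at 5 mM and an ascorbic acid salt at 50 µg/mL, and the cells were kept at 37 °C in 5% CO2. RNA of integrity number 7.0 or higher went into stranded poly(A)-selected libraries, per the labels' protocols. The batch entry of the labels is the same for every library.

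Per the submitters' processing notes, reads were trimmed with cutadapt 1.10, checked with FastQC 0.10.1, aligned with HISAT2 2.0 and assembled and quantified with StringTie 1.3.4, and edgeR is listed without a version or a stated role. The authors deposited 1 FPKM value (fragments scaled to transcript length and to all mapped fragments) per gene and library, rounded to 2 decimals. The notes name the builds GRCm38 and mm10, whereas the gene identifiers of the table belong to the annotation of the C57BL/6NJ strain. Coordinates are therefore not used here, and gene symbols are those that the table pairs with its identifiers. The authors also deposited 1 p-value and 1 q-value per gene without stating which groups they compare. The 3112 genes marked significant there, of which 2696 were among the genes tested, reach p-values of up to 0.05 and q-values of up to 0.21, and these columns were not used here for any comparison.

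The sequencing depth of the libraries is unknown, because the table holds no counts. Whether the low values fall on steps of whole reads was checked from the ratios of FPKM between libraries, for genes at 0.2 to 1 FPKM in both: in the 66 pairs of libraries, the fullest bin of the natural log ratio, 0.02 wide, held between 2.02% and 3.55% of the genes, so no such steps were seen. No limit can thus be put on a value of 0, and a gene without a value above 0 in an arm is reported as listed at 0, without a fold. Of the 39032 genes in the table, 17203 are at 0 in all libraries and 9758 carry no symbol. In 50 cases a symbol occurs again under another identifier, and these genes were kept apart by identifier. X-linked genes such as Bgn and Phex, and transcripts of the mitochondrial genome other than mt-Nd6, were not analysed here.

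FPKM values were transformed as log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 libraries were tested, which left 11548 genes, 1083 of them without a symbol. The pseudocount of 1 pulls the log2 changes of genes at low FPKM toward 0, so FPKM means with their SD are given beside them. One linear model with the 4 arms was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with a variance prior that follows the mean level, 8 residual and 2.5 prior degrees of freedom. The 6 comparisons were RSPO2 against Control, BMP2 against Control, BMP2+RSPO2 against Control, BMP2+RSPO2 against BMP2, BMP2+RSPO2 against RSPO2, and the interaction, which is the log2 effect of RSPO2 in the presence of BMP2 minus its log2 effect without BMP2. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called when its adjusted p was under 0.05. All adjusted p-values of genes and lists below come from limma, and the SE of a log2 change is the one of that fit.

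Before the data were examined, 27 gene lists with 519 entries were fixed, of which 483 are in the table and 1 entry stands in more than 1 list. The 22 lists with at least 5 tested members were tested with camera of limma at its preset correlation of 0.01, which compares a list with the other tested genes, and the p-values were adjusted over the lists within a comparison. The same test was run with the correlation estimated from the residuals of each list, and with fry of limma, which asks whether the members of a list move on balance one way. The number of list members called was counted both over all genes tested and adjusted over the list alone. Gene set enrichment used a one-sided hypergeometric (Fisher's exact) test on the functional terms that the table itself gives, with 9194 annotated tested genes as background and 1914 terms of 10 to 500 of them, adjusted over the terms.

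The genes named were also fixed beforehand by rule: a panel of 14 genes (Runx2, Sp7, Alpl, Bglap, Ibsp, Dmp1, Axin2, Lef1, Znrf3, Nkd2, Id1, Smad6, Dlx5 and Tnfrsf11b), of which Bglap is not in the table; the 6 largest rises and the 6 largest falls among called genes whose groups do not overlap, without predicted genes; and from each called list up to 3 called members with the smallest p. Genes named outside this rule are members of the lists given as examples or are marked as chosen after their values were seen.

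The replicate numbers were checked for pairing before any calls were compared. For each pair of arms, the deviations of same-numbered libraries from their arm means were correlated across genes, and 16 of 18 such correlations were above 0.1 (lowest −0.125, highest 0.631). All 3 correlations were above 0.1 for RSPO2 against Control, BMP2+RSPO2 against Control and BMP2+RSPO2 against BMP2, so the blocked value is printed for these comparisons, and for the interaction, where it changes a call of the panel or of a list. Counts of genes and the named genes were recomputed with a pseudocount of 0.1, without the filter (21829 genes), with a filter of 5 FPKM (7796 genes), with median-of-ratios scaling, with quantile normalization, with limma's robust variance model, with the replicate number as a block, with only the arms compared in the fit, with an added size threshold of 1 on the log2 scale for the counts, and without each library in turn. List tests were repeated with the pseudocount of 0.1, quantile normalization, median-of-ratios scaling, the replicate block and each library left out, and with the other set tests above. The correlations of effects were repeated with that pseudocount, both filters, quantile normalization, Spearman's rho and each library left out. Alternatives added after seeing the data were replicates 2 and 3 only, scaling to the FPKM total of protein-coding genes, and, for genes alone, a batch term for the first replicates and library weights of limma.

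The pipeline was tested on simulated data made from the means and spreads of these libraries, with 200 of 11548 genes changed. At a log2 change of 1 the fit recovered 61% of the changed genes both for RSPO2 against Control and for BMP2+RSPO2 against BMP2, and at a log2 change of 2 it recovered 88% and 91%. False calls made up 3.87% and 3.80% of the calls. A shift of 0.5 added to the osteoblast list was called in both simulated comparisons (adjusted p = 5.27e-10 and 0.000335), with 0 other lists of 22 called by camera. The simulated genes and libraries were drawn independently, whereas list members and same-numbered libraries correlate in the data. These rates therefore do not cover false calls that such correlation would give. Figures were drawn with matplotlib 3.10.9 in Python 3.11.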

Results

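The data are FPKM values of 12 RNA sequencing libraries from MC3T3-E1 subclone 14, a mouse pre-osteoblast line that forms mineralized matrix in osteogenic medium. Cells were grown for 5 days with vehicle, with R-spondin 2 (RSPO2, a secreted enhancer of Wnt signalling) at 200 ng/ml, with bone morphogenetic protein 2 (BMP2) at 100 ng/ml, or with both, with 3 independent biological replicates per arm. The series asks whether both proteins together drive osteoblast differentiation further than BMP2 does. Depth is unknown, since the table holds no counts, and 10681 to 11379 genes were at 1 FPKM or more per library. The Rspo2 transcript itself was measured at 2.09 ± 0.380 FPKM in Control, 1.19 ± 0.400 with RSPO2, 1.14 ± 0.599 with BMP2 and 0.0900 ± 0.123 with both (mean ± SD, n = 3 in every arm here and below). Bmp2 was listed at 0 in all 12 libraries. Lgr4, which encodes a receptor for R-spondins, was present in every arm, from 2.69 ± 0.342 FPKM with RSPO2 to 6.59 ± 0.265 with both.

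Some libraries stood apart from their arms in RNA composition. In BMP2+RSPO2 replicate 1, RNAs made by RNA polymerase III, such as Rn7s1, made up 19.1% of the summed FPKM, against 2.30% in RSPO2 replicate 3 and 0.179% to 0.656% in the other libraries. Replication-dependent histone genes, whose mRNAs lack poly(A) tails, had a median of 35.1 FPKM in that library and of 0.340 to 2 FPKM in the other 11. The FPKM of that library summed to 635139, against 322074 to 380507 elsewhere, and its 10 most abundant genes held 57.8% of the sum, against 11.4% to 19.8%. Cytosolic ribosomal protein genes had a median of 285 FPKM there, 510 and 562 FPKM in the other BMP2+RSPO2 libraries, and 656 to 792 FPKM in the other arms. The first replicate of every arm also differed from replicates 2 and 3 in proliferation genes. All 26 tested cell cycle genes were higher in replicate 1 of each arm, with a median log2 difference of 1.96 in Control, 2.19 with RSPO2, 1.09 with BMP2 and 1.47 with both. The first principal component of the tested genes held 37.4% of the variance and the second 25.7%. Because of these differences, each count of changed genes was also made from replicates 2 and 3 alone, a setting chosen after seeing the data.

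**Figure D1:**
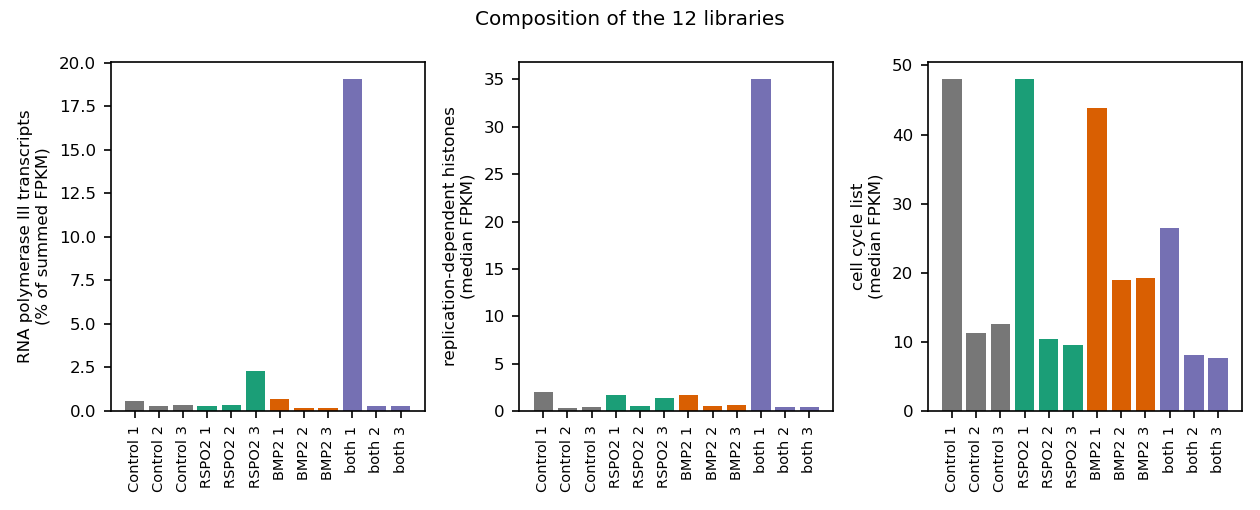
Bars show, for each of the 12 libraries, the percent of summed FPKM from RNA polymerase III transcripts, the median FPKM of replication-dependent histone genes, and the median FPKM of the cell cycle list. BMP2+RSPO2 replicate 1 reaches 19.1% and 35.1 FPKM in the first and second panels, and the first replicate of each arm has the highest cell cycle median of its arm, from 26.4 to 48.1 FPKM.

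RSPO2 alone raised targets of canonical Wnt signalling. Nkd2, a feedback inhibitor of the Wnt pathway, rose from 1.26 ± 0.465 to 6.34 ± 0.365 FPKM (log2 change 1.72, SE 0.17, adjusted p = 0.00894). The neural transcription factor gene Neurog2 rose from 0.303 ± 0.272 to 3.09 ± 0.846 FPKM (log2 1.65, adjusted p = 0.0231), and Igfbp2, which encodes a binding protein of insulin-like growth factors, from 63.4 ± 1.12 to 138 ± 15.8 FPKM (log2 1.1, adjusted p = 0.0383). The prostaglandin F receptor gene Ptgfr fell from 21.8 ± 2.60 to 7.27 ± 0.675 FPKM (log2 −1.46, adjusted p = 0.0338), and Otor fell from 1.81 ± 0.155 to 0.347 ± 0.0611 FPKM (log2 −1.06, adjusted p = 0.0338). The other called genes with a symbol were Slc12a7, a potassium-chloride cotransporter (log2 1.21, adjusted p = 0.0408), the acid-sensing channel Asic1 (1.06, adjusted p = 0.0383) and the transcription factor Ets2 (0.96, adjusted p = 0.0383).

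Of 17 tested canonical Wnt target genes, 1 rose over all genes tested and 9 rose adjusted over the list alone. Their median was 0.48 (camera adjusted p = 2.62e-13, and adjusted p = 0.000723 with an estimated correlation). Axin2, the classical Wnt target, was at 4.17 ± 1.00 FPKM in Control and 11.7 ± 2.44 with RSPO2 (log2 1.3, adjusted p = 0.159, and 0.0312 with the replicate number as a block). Notum was at 8.53 ± 0.713 and 20.7 ± 2.97 FPKM, and Lef1 at 1.85 ± 0.0643 and 3.55 ± 0.398 (log2 0.67, adjusted p = 0.607). Osteoblast genes as a group were lower: 0 of 17 passed over all genes tested and 2 fell adjusted over the list alone. Their median was −0.35 (camera adjusted p = 7.95e-09, and adjusted p = 0.105 with an estimated correlation). Ibsp, which encodes bone sialoprotein, was at 645 ± 171 FPKM in Control and 308 ± 77.2 with RSPO2 (log2 −1.06, adjusted p = 0.407). BMP-SMAD target genes had a median of −0.28, with 2 rising and 3 falling adjusted over the list alone and 0 of 21 over all genes tested (camera adjusted p = 3.63e-05, and adjusted p = 0.0103 with an estimated correlation). The inhibitor of differentiation gene Id1 was at 1.19 ± 0.457 FPKM in Control and 0.337 ± 0.143 with RSPO2 (log2 −0.70, adjusted p = 0.67). Chondrocyte genes had a median of −0.53, with 1 of 8 falling adjusted over the list alone (camera adjusted p = 2.94e-05, and adjusted p = 0.0103 with an estimated correlation).

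Genes for BMP and TGF-β ligands and receptors had a median of 0.12, with 4 of 23 rising adjusted over the list alone (camera adjusted p = 5.42e-04, and adjusted p = 0.0421 with an estimated correlation). The list of 25 fibrillar and interstitial matrix genes (median 0.06, camera adjusted p = 8.90e-04) and that of 16 cholesterol synthesis genes (median −0.15, 1.16e-04) were called as well, but with an estimated correlation their adjusted p = 0.239 and 0.36. The 8 osteoclast regulators made by osteoblasts (median −0.13, camera adjusted p = 0.043) and the 23 cytosolic ribosomal protein genes (median −0.10, camera adjusted p = 0.0496) lost their calls with an estimated correlation (adjusted p = 0.135 and 0.792) and after quantile normalization (0.0977 and 0.277). The osteoclast regulators also lost theirs with the replicate block (0.184). The 26 cell cycle genes had a median of −0.18, with 1 of them higher (camera adjusted p = 0.13, 1.63e-04 with the replicate block, and 0.856 with an estimated correlation).

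In all, limma called 9 of 11548 genes between RSPO2 and Control, 7 higher and 2 lower, with 418 at an unadjusted p under 0.05. All 9 have groups that do not overlap, as do 9.33% of all tested genes, where chance gives 10%. The count of called genes rests on single libraries: it was 3 without Control replicate 1, 0 without Control replicate 2, and 2 without Control replicate 3. It was 3, 1 and 0 without RSPO2 replicates 1, 2 and 3, 4 and 1 without BMP2 replicates 2 and 3, and 21, 1 and 1 without BMP2+RSPO2 replicates 1, 2 and 3. It was 26 with the replicate block, 0 with a pseudocount of 0.1, and 195 (126 rises and 69 falls) from replicates 2 and 3 alone, which hold 8 of the 9 genes. In that smaller set Axin2 (log2 1.31, adjusted p = 0.00481), Lef1 (0.69, adjusted p = 0.0427) and Ibsp (−1.10, adjusted p = 0.0165) were called. Each of the 8 named genes lost its call without at least 1 library, Nkd2 in 3 of the 12 fits (highest adjusted p = 0.0907) and the others in 7 to 11, and 4 of the 8 were called under each scaling (quantile normalization, median-of-ratios and protein-coding scaling).

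BMP2 alone raised osteoblast genes and its own feedback targets. Alpl, the alkaline phosphatase of mineralizing cells, rose from 8.71 ± 0.455 to 20.0 ± 2.81 FPKM (log2 1.1, SE 0.19, adjusted p = 0.018), and Ibsp from 645 ± 171 to 1829 ± 290 FPKM (log2 1.53, SE 0.26, adjusted p = 0.0173). Smad6, an inhibitor of BMP signalling that BMP induces, rose from 4.13 ± 0.808 to 9.91 ± 1.06 FPKM (log2 1.1, SE 0.16, adjusted p = 0.0086). Nkd2 fell from 1.26 ± 0.465 to 0.153 ± 0.157 FPKM (log2 −0.96, SE 0.17, adjusted p = 0.0179). The smooth muscle actin gene Acta2 fell from 1190 ± 89.2 to 599 ± 20.5 FPKM (log2 −0.99, SE 0.13, adjusted p = 0.00415). The osteoblast transcription factors Runx2 (log2 0.38, adjusted p = 0.384) and Sp7 (0.82, 0.271) were not called. Nor were Dmp1 (2.56, SE 1.95, 0.835), Axin2 (−0.71, 0.283), Lef1 (−0.43, 0.474), Znrf3 (0.04, 0.999), Id1 (0.92, 0.0671), Dlx5 (0.62, 0.323) and Tnfrsf11b (osteoprotegerin, −0.10, 0.998). Dmp1, Axin2 and Id1 were called without the first replicates (0.00269 to 0.0121). The calls of Alpl (adjusted p = 0.0559 to 0.074) and Ibsp (0.0534 to 0.0688) ended without any 1 Control or BMP2 replicate, except Control replicate 3 for Ibsp. That of Nkd2 ended without Control replicate 1 or BMP2 replicates 2 or 3 (0.065 to 0.088), while Smad6 and Acta2 were called without each library in turn.

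The 6 largest rises were Slc36a2, an amino acid transporter, from 3.66 ± 1.62 to 30.1 ± 3.71 FPKM (log2 2.80, adjusted p = 0.00247), the metalloprotease gene Adam12 from 1.60 ± 0.366 to 13.6 ± 0.609 FPKM (2.50, adjusted p = 9.73e-06), and the cartilage collagen Col2a1 (2.47, adjusted p = 0.0161), followed by 3 more. These were Cd200 (2.19, adjusted p = 0.00415), the cysteine dioxygenase gene Cdo1 (2.12, adjusted p = 0.018) and Gpr141 (1.84, adjusted p = 0.0013). The 6 largest falls were Enpp2, which encodes autotaxin, from 30.5 ± 18.1 to 2.10 ± 1.40 FPKM (log2 −3.29, adjusted p = 0.00239), the neurturin receptor gene Gfra2 from 16.4 ± 5.93 to 0.817 ± 0.350 FPKM (−3.22, adjusted p = 4.41e-05), and the fast skeletal troponin gene Tnnc2 (−3.16, adjusted p = 0.000765), and then 3 others. Those were Apod (−3.01, adjusted p = 0.00147), Itgbl1 (−2.67, adjusted p = 0.000145) and Nov (−2.51, adjusted p = 0.0274). Of these 12, Col2a1 lost its call without Control replicate 1 or BMP2 replicates 2 or 3 (highest adjusted p = 0.0847). Cdo1 lost it without Control replicates 1 or 2 or any BMP2 replicate, and Nov without Control replicates 1 or 2, RSPO2 replicate 2 or BMP2 replicates 2 or 3.

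Of 17 osteoblast genes, 3 rose (Alpl, Ibsp and the cytokine receptor gene Lifr, log2 1.04, adjusted p = 0.00196) and 11 rose adjusted over the list alone. Their median was 0.95 (camera adjusted p = 4.21e-19, and adjusted p = 0.0167 with an estimated correlation). Of 21 BMP-SMAD targets, Smad6 and Atoh8 (log2 1.25, adjusted p = 0.0161) were among those that rose, and Grem1, a BMP antagonist, fell (−1.99, adjusted p = 0.00231), with 11 rising and 4 falling adjusted over the list alone. Their median was 0.52 (camera adjusted p = 2.22e-09, and adjusted p = 0.0026 with an estimated correlation). Smooth muscle and contractile genes were lower, with 3 of 10 falling (Itga8, Acta2 and Lmod1), 7 adjusted over the list alone. Their median was −0.53 (camera adjusted p = 2.22e-09, and adjusted p = 0.00288 with an estimated correlation). Chondrocyte genes had a median of 0.55, with Col2a1 called of 8 and 3 rising adjusted over the list alone (camera adjusted p = 6.67e-05, and adjusted p = 0.0142 with an estimated correlation). Of 25 fibrillar and interstitial matrix genes, 5 fell, among them the fibrillin genes Fbn1 (9.10 ± 1.41 to 1.06 ± 0.104 FPKM, log2 −2.29, adjusted p = 3.95e-05) and Fbn2 (−2.26, adjusted p = 0.00113), and 9 fell and 1 rose adjusted over the list alone. Their median was −0.37 (camera adjusted p = 6.77e-05, and adjusted p = 0.152 with an estimated correlation). Of 23 BMP and TGF-β ligand and receptor genes, 4 fell, with the ligand gene Gdf6 (−2.20, adjusted p = 0.000765) and the receptor gene Tgfbr2 (−1.09, adjusted p = 0.00247) among them, and 2 rose and 5 fell adjusted over the list alone. Their median was −0.13 (camera adjusted p = 0.0196, and adjusted p = 0.152 with an estimated correlation).

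Of 17 canonical Wnt targets, Nkd2 and the growth factor gene Fgf18 (log2 −1.32) fell, and the list was not called (median −0.43, camera adjusted p = 0.173). Of 26 Wnt ligands, receptors and modulators, 4 fell, among them the secreted Wnt antagonist Sfrp2 (log2 −1.25, adjusted p = 0.00173), Wnt7b (−1.46, adjusted p = 0.00405) and the receptor gene Fzd2 (−0.74, adjusted p = 0.0274). The call of Fzd2 ended without any 1 of the Control or BMP2 replicates (highest adjusted p = 0.118). As a whole that list was not called (camera adjusted p = 0.51). Hypoxia and glycolysis genes had a median of −0.55 with 1 of 13 called, Pfkp (−0.78, adjusted p = 0.0304), and the list was called by camera (adjusted p = 0.00162, and adjusted p = 0.557 with an estimated correlation). Inflammation genes (median −0.16, camera adjusted p = 0.0453, and adjusted p = 0.301 with an estimated correlation) held 2 falls of 8, Vcam1 and Il1rl1. Interferon response genes held 0 calls of 8 over all genes tested and 2 falls adjusted over the list alone. Their median was −0.34 (camera adjusted p = 0.0344, and 0.304 with an estimated correlation). All 26 cell cycle genes were higher, with 0 called over all genes tested or the list alone. Their median was 0.35 (camera adjusted p = 0.00562, and 0.688 with an estimated correlation). These genes set replicate 1 of each arm apart, and without the first replicates 23 rose. With 1 library left out, the calls of Pfkp (7 of the 12 fits, highest adjusted p = 0.125), Il1rl1 (7, 0.156), Lmod1 (6, 0.0931) and Vcam1 (4, 0.111) ended. Of the 34 called genes of the naming rule, 22 were called without each library in turn and 30 under each scaling.

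Over all genes tested, limma called 175 between BMP2 and Control, 59 higher and 116 lower, and none of the 175 had overlapping groups, against 20.8% of all tested genes without overlap where chance gives 10%. The count was 65, 87 and 93 without Control replicates 1, 2 and 3, 75 and 66 without BMP2 replicates 2 and 3, and 403 without BMP2+RSPO2 replicate 1. Replicates 2 and 3 alone gave 963 genes (433 rises and 530 falls), which hold 169 of the 175. Falling genes were enriched for the term extracellular region, with 41 of its 429 background genes where 4.95 were expected (adjusted p = 2.05e-24), and for growth factor activity, with 7 of 44 (adjusted p = 0.000143).

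**Figure D2:**
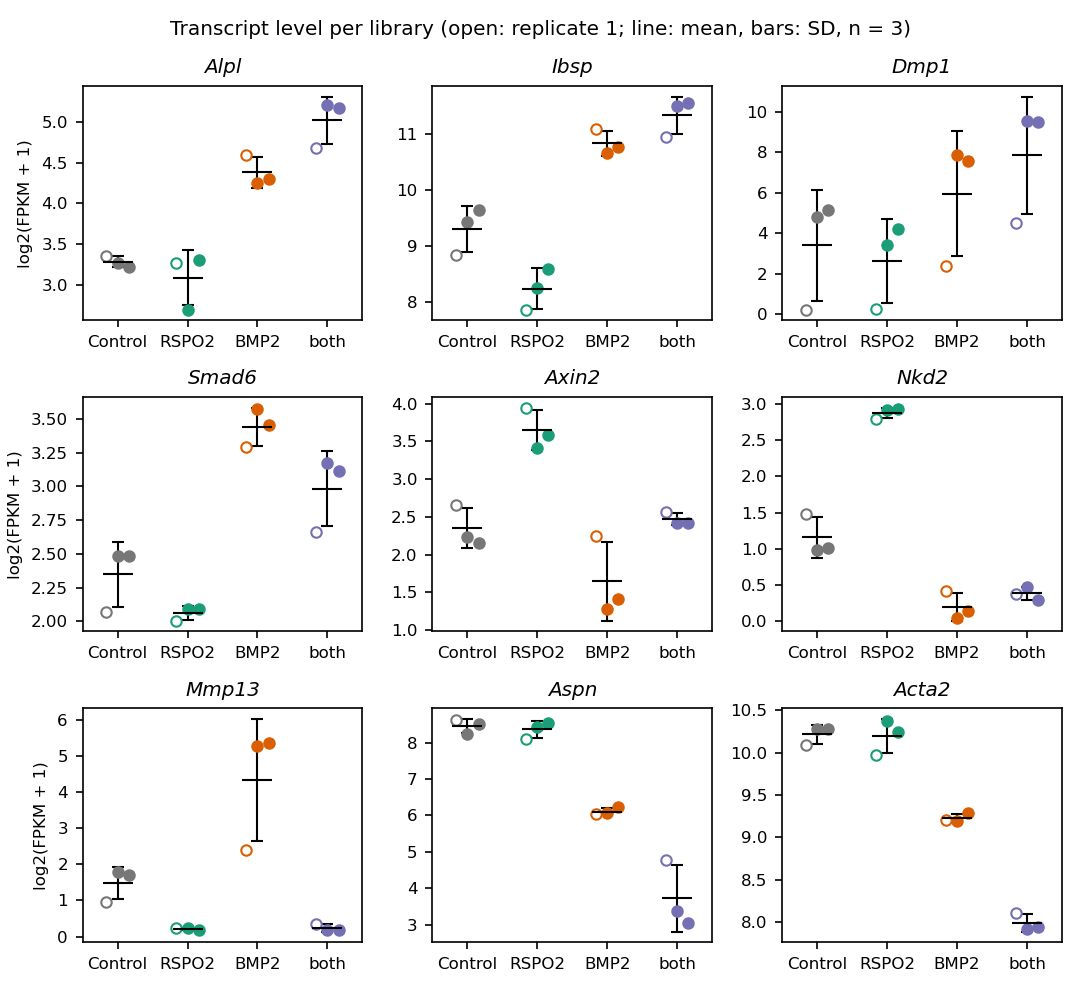
Points show log2(FPKM + 1) of 9 genes in each library of the 4 arms, with open points for replicate 1, a line for the mean and bars for the SD (n = 3). Alpl and Ibsp have their highest means with both proteins, at 31.9 and 2610 FPKM, Mmp13 is high with BMP2 alone (27.6 FPKM), and Acta2 and Aspn have their lowest means with both, at 253 and 14.3 FPKM.

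With both proteins, osteoblast genes stood higher against Control. Alpl rose from 8.71 ± 0.455 to 31.9 ± 6.24 FPKM (log2 1.74, SE 0.19, adjusted p = 0.000322) and Ibsp from 645 ± 171 to 2610 ± 554 FPKM (2.03, SE 0.26, adjusted p = 0.000741). Sp7 rose from 124 ± 35.6 to 262 ± 79.3 FPKM (1.06, SE 0.28, adjusted p = 0.0222) and Runx2 from 29.9 ± 4.71 to 43.6 ± 4.01 FPKM (0.54, SE 0.15, adjusted p = 0.0265). Id1 rose from 1.19 ± 0.457 to 4.03 ± 1.15 FPKM (1.20, SE 0.21, adjusted p = 0.00346) and Smad6 from 4.13 ± 0.808 to 7.01 ± 1.46 FPKM (0.64, SE 0.16, adjusted p = 0.019). Nkd2 fell from 1.26 ± 0.465 to 0.307 ± 0.0802 FPKM (−0.78, SE 0.17, adjusted p = 0.00888), a call that ended after quantile normalization. Not called were Dmp1, an osteocyte matrix gene at 20.7 ± 18.2 and 495 ± 410 FPKM (4.44, SE 1.95, adjusted p = 0.121, and 1.37e-04 with the replicate block) and Dlx5 (0.66, adjusted p = 0.0608, and 0.0295 with the replicate block). Axin2 (0.11, 0.756), Lef1 (0.18, 0.505), Znrf3 (0.29, 0.316) and Tnfrsf11b (0.42, 0.118) were not called either. Alpl, Ibsp and Id1 were called without each library in turn. The calls of Sp7, Runx2 and Smad6 ended without Control replicate 1 (adjusted p = 0.0823, 0.0979 and 0.07) or BMP2+RSPO2 replicate 3 (0.063, 0.0514 and 0.0544). Those of Sp7 and Smad6 also ended without BMP2+RSPO2 replicate 2 (0.0671 and 0.0602), and that of Runx2 without BMP2+RSPO2 replicate 1 (0.0629).

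The largest rises against Control were Slc36a2, to 55.9 ± 17.3 FPKM (log2 3.62, SE 0.34, adjusted p = 0.000113), and Cd200, to 20.5 ± 6.82 FPKM (3.39, SE 0.29, adjusted p = 6.83e-05). Next came the cartilage collagen Col11a2 (2.86, SE 0.56, adjusted p = 0.00616), the sphingomyelin synthase gene Sgms2 (2.80, SE 0.27, adjusted p = 0.000136), Adam12 (2.79, SE 0.12, adjusted p = 1.52e-06) and Cdo1 (2.78, SE 0.37, adjusted p = 0.000869). The largest falls were Aspn, which encodes the matrix proteoglycan asporin, from 353 ± 47.6 to 14.3 ± 10.5 FPKM (−4.73, SE 0.36, adjusted p = 3.51e-05), Tnnc2 (−4.36, SE 0.30, adjusted p = 2.85e-05) and Gfra2 (−3.77, SE 0.21, adjusted p = 8.28e-06). They were followed by Igfbp2, from 63.4 ± 1.12 to 5.91 ± 0.329 FPKM (−3.22, SE 0.15, adjusted p = 2.38e-06), Apod (−3.12, SE 0.32, adjusted p = 0.000213) and the matrix proteoglycan gene Ogn (−3.08, SE 0.32, adjusted p = 0.000248). These 12 genes were called without each library in turn and under each scaling.

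Of 17 osteoblast genes, 15 rose and 1, the proteoglycan gene Omd, fell (log2 −1.21, adjusted p = 0.0147), with the same counts adjusted over the list alone. After quantile normalization 12 rose and 0 fell, and with median-of-ratios scaling 15 and 0. Their median was 1.13 (camera adjusted p = 5.95e-17, and adjusted p = 0.0314 with an estimated correlation). Among the 15 were Lifr (1.53, adjusted p = 3.67e-05), Col1a1 (1.12, adjusted p = 0.00961) and the osteocalcin gene Bglap2 (3.21, adjusted p = 0.0439), whose near-identical neighbours make its level uncertain. Bglap2 was at 57.9 FPKM in BMP2+RSPO2 replicate 1 and at 1380 and 1297 in replicates 2 and 3, and its log2 change was 4.71 without replicate 1. Osteocyte genes had 3 of 6 rising, Cpe (2.04, adjusted p = 0.00496), the chemokine receptor gene Ackr3 (1.03, adjusted p = 0.0178) and Irx5 (0.80, adjusted p = 0.0194), and 1 falling adjusted over the list alone. Their median was 0.92 (camera adjusted p = 0.00446, and adjusted p = 0.0539 with an estimated correlation). With 1 library left out, the calls of Ackr3 (3 of the 12 fits, highest adjusted p = 0.0608) and Irx5 (4, 0.0612) ended, while that of Cpe held. Of 21 BMP-SMAD targets, 9 rose, among them Dlx3 (1.38, adjusted p = 0.00235), and 3 fell, among them Grem1 (−1.57, adjusted p = 0.00149), with 12 and 4 adjusted over the list alone. Their median was 0.51 (camera adjusted p = 4.87e-07, and adjusted p = 0.00556 with an estimated correlation). Smooth muscle and contractile genes fell in 9 of 10, both over all genes and adjusted over the list alone. Acta2 was at 253 ± 18.6 FPKM (−2.23, adjusted p = 9.5e-06) and the myosin light chain gene Myl9 at 64.9 ± 6.08 FPKM with both (−1.93, adjusted p = 1.94e-05). Their median was −1.51 (camera adjusted p = 1.28e-07, and adjusted p = 0.00556 with an estimated correlation).

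Of 17 canonical Wnt targets, 4 rose, among them Wisp1 (log2 1.25, adjusted p = 0.000779), Wif1 (2.54, adjusted p = 0.0112) and the transcription factor Tcf7 (0.80, adjusted p = 0.00633), and 3 fell, among them Wisp2 (−2.40, adjusted p = 0.00116). After quantile normalization 5 rose and 1 fell, and with median-of-ratios scaling 5 and 2. The list median was 0.11 (camera adjusted p = 0.0207, adjusted p = 0.091 with an estimated correlation, and 0.085 after quantile normalization). Quantile normalization, median-of-ratios and protein-coding scaling gave medians of 0.32, 0.35 and 0.35. Chondrocyte genes held 3 rises of 8, Col2a1, Col11a2 and Col10a1, a collagen of hypertrophic cartilage, which was at 0.0233 ± 0.0252 FPKM in Control and 3.12 ± 2.53 with both (1.71, adjusted p = 0.0319). Their median was 0.02 (camera adjusted p = 0.0207, adjusted p = 0.091 with an estimated correlation, and 0.0685 after quantile normalization). Of 26 Wnt ligands, receptors and modulators, 2 rose and 8 fell, with Sfrp2 at 61.2 ± 5.04 and 15.2 ± 1.87 FPKM (−1.95, adjusted p = 2.85e-05). The list was not called (camera adjusted p = 0.541), its camera direction being up against a median of −0.04 and a mean of −0.20. It held 5 rises and 4 falls after quantile normalization (median 0.18) and 3 and 4 with median-of-ratios scaling (0.15), so the excess of falls depends on the scaling. Of 23 BMP and TGF-β ligands and receptors, 3 rose and 8 fell, with Gdf6 (−2.37, adjusted p = 9.8e-05) and Fstl1 (−1.40, adjusted p = 0.000133) among the falls, and the list was not called (adjusted p = 0.526). Tendon and ligament genes held 3 falls of 7, Aspn, Fmod (−1.37, adjusted p = 0.000745) and Mkx, and 5 adjusted over the list alone. Their median was −0.62 (camera adjusted p = 0.056, 0.0256 with the replicate block, 0.039 after quantile normalization, and 0.212 with an estimated correlation). Fibrillar and interstitial matrix genes held 2 rises and 12 falls of 25, with Col3a1 at 758 ± 17.8 and 116 ± 16.8 FPKM (−2.70, adjusted p = 2.85e-05) and Fbn1 (−2.44, adjusted p = 8.28e-06). Their median was −0.54 (camera adjusted p = 0.0641, 0.0469 after quantile normalization, and 0.587 with an estimated correlation). Mineralization and phosphate genes held 0 rises and 2 falls of 11, Nt5e (−1.04, adjusted p = 0.00233) and Slc20a2 (−0.57, adjusted p = 0.00685), against a median of 0.64 (camera adjusted p = 0.056, 0.00596 with the replicate block, and 0.587 with an estimated correlation). The calls of Mkx (7 of the 12 fits, highest adjusted p = 0.12), Col10a1 (5, 0.0964) and Col2a1 (4, 0.102) ended with 1 library left out.

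Groups that differ between the libraries in RNA composition also moved in this comparison. Of 23 cytosolic ribosomal protein genes, 18 fell, and 23 adjusted over the list alone. Their median was −0.78 (camera adjusted p = 1.26e-04, and adjusted p = 0.587 with an estimated correlation), and they were lowest in BMP2+RSPO2 replicate 1. After quantile normalization 0 of the 23 fell and with median-of-ratios scaling 1 did, with list medians of −0.43 and −0.50, while replicates 2 and 3 alone gave 21 falls. Hypoxia and glycolysis genes held 6 falls of 13, and 9 adjusted over the list alone, but 1 under either scaling and 1 from replicates 2 and 3 alone. Their median was −1.18 (camera adjusted p = 0.0145, and adjusted p = 0.618 with an estimated correlation). Of 15 immediate early genes, Klf4 (log2 1.33, adjusted p = 0.00874) and Klf2 (0.74, adjusted p = 0.0448) rose and Jun fell (−1.26, adjusted p = 0.000142). Their median was 0.06 (camera adjusted p = 0.0191, adjusted p = 0.587 with an estimated correlation, and 0.146 after quantile normalization). All 26 cell cycle genes were lower (median −0.69), with 0 called over all genes tested or the list alone. Without the first replicates, 25 fell. With all libraries camera, which works on t statistics, gave the direction up (adjusted p = 0.836, 0.00454 with the replicate block, 0.958 with an estimated correlation). Notch genes held 1 rise, Hes1 (1.59, adjusted p = 0.00083), and 3 falls of 6 (camera adjusted p = 0.836). The lists of interferon response and inflammation genes, each with 4 falls of 8, were not called (camera adjusted p = 0.131 for both). Nor were cholesterol synthesis genes, with 7 of 16 falling (0.221), matrix proteases and inhibitors, with 2 rises and 1 fall of 14 (0.795), and ER stress genes, with 3 falls of 16 (0.526). Under either scaling cholesterol synthesis genes held 0 falls, and ER stress genes 2 rises and 0 falls. After quantile normalization, interferon response and inflammation genes held 2 falls each and Notch genes 1. For the matrix protease and ER stress lists the camera direction was up, against medians of −0.35 and −0.11. The call of Klf2 ended in 9 of the 12 fits with 1 library left out (highest adjusted p = 0.154). Of the 71 called genes of the naming rule, 56 were called without each library in turn and 55 under each scaling.

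In this comparison, limma called 2656 genes, 421 higher and 2235 lower. Of these, 2637 do not overlap, against 43.96% of all tested genes without overlap where chance gives 10%. The median tested gene was shifted by −0.26 on the log2 scale, and quantile normalization, which removes this shift, gave 800 rises and 826 falls, with 1243 genes called in both settings. The count was 1595 without Control replicate 1, 1712 without Control replicate 3 and 3994 from replicates 2 and 3 alone (856 rises and 3138 falls), which hold 2380 of the 2656. Rising genes were enriched for the term proteinaceous extracellular matrix (22 of 127 genes where 4.93 were expected, adjusted p = 5.47e-06), for ion transport (24 of 183, adjusted p = 0.000143) and for biomineral tissue development (5 of 12, adjusted p = 0.0111). Falling genes were enriched for extracellular region (159 of 429 where 89.0 were expected, adjusted p = 7.7e-13). The terms ribosome (85 of 150, adjusted p = 5.38e-19) among the falls and ossification (11 of 51, adjusted p = 0.00181) among the rises were not enriched after quantile normalization.

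Adding RSPO2 to BMP2 lowered contractile genes as a group. Mmp13, the collagenase of the osteoblast lineage, was at 27.6 ± 20.2 FPKM with BMP2 and fell to 0.180 ± 0.0866 FPKM with both (log2 −4.12, SE 0.63, adjusted p = 0.0106). Aspn fell from 68.1 ± 5.07 to 14.3 ± 10.5 FPKM (−2.38, SE 0.36, adjusted p = 0.00915) and Ptgfr from 29.0 ± 4.88 to 5.15 ± 1.68 FPKM (−2.30, SE 0.19, adjusted p = 0.000609). Wisp2 fell from 11.9 ± 0.551 to 1.86 ± 0.462 FPKM (−2.18, SE 0.33, adjusted p = 0.0102). The proton channel gene Hvcn1 (−2.08, SE 0.48, adjusted p = 0.0418) and the pentraxin gene Ptx3 (−2.06, SE 0.29, adjusted p = 0.00651) fell as well. The largest rises were the collagen receptor gene Ddr2, from 11.6 ± 1.43 to 53.0 ± 8.45 FPKM (2.10, SE 0.42, adjusted p = 0.0277), and Prex1, an activator of Rac, from 1.75 ± 0.166 to 11.05 ± 3.04 FPKM (2.10, SE 0.21, adjusted p = 0.00109). The microRNA loci Mir3100 (1.56, SE 0.31, adjusted p = 0.0253) and Mir3074-1 (1.53, SE 0.34, adjusted p = 0.0383), both under 4 FPKM, rose as well, as did Specc1 (1.51, SE 0.22, adjusted p = 0.00852) and Sgms2, from 59.8 ± 8.65 to 168 ± 26.1 FPKM (1.48, SE 0.27, adjusted p = 0.0199). Prex1, Ptgfr, Ptx3 and Specc1 were called without each library in turn. The calls of Mmp13 and Wisp2 ended without BMP2 replicates 2 or 3 and that of Aspn without BMP2 replicate 3 (highest adjusted p = 0.0518). That of Ddr2 ended without any BMP2 replicate or BMP2+RSPO2 replicate 2 (highest 0.105), and that of Sgms2 without BMP2 replicates 2 or 3 or BMP2+RSPO2 replicate 2.

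None of the 13 tested panel genes was called between these arms with all 12 libraries. Alpl was at 20.0 ± 2.81 and 31.9 ± 6.24 FPKM (log2 0.64, SE 0.19, adjusted p = 0.0799) and Ibsp at 1829 ± 290 and 2610 ± 554 (0.50, SE 0.26, 0.25). Sp7 was at 215 ± 20.2 and 262 ± 79.3 (0.23, SE 0.28, 0.606) and Runx2 at 39.0 ± 4.57 and 43.6 ± 4.01 (0.16, SE 0.15, 0.509). The log2 change was 0.82 for Axin2 (adjusted p = 0.0792, and 0.0155 with the replicate block), 1.89 for Dmp1 (SE 1.95, 0.548, and 0.0164 with the replicate block) and −0.46 for Smad6 (0.117, and 0.0270 with the replicate block). It was 0.61 for Lef1 (0.0872), 0.25 for Znrf3 (0.446), 0.19 for Nkd2 (0.481), 0.28 for Id1 (0.4), 0.04 for Dlx5 (0.927) and 0.51 for Tnfrsf11b (0.117).

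As a group, the 17 osteoblast genes were higher with both proteins than with BMP2, with a median of 0.32 and 14 of 17 positive, 1 of them called over all genes tested and adjusted over the list alone, Lifr (log2 0.49, adjusted p = 0.0446). That call ended in 10 of the 12 fits with 1 library left out (highest adjusted p = 0.125). The median was 0.37, 0.53 and 0.57 with quantile normalization, median-of-ratios and protein-coding scaling, with 1 rise after quantile normalization and 2 with median-of-ratios scaling. From replicates 2 and 3 alone it was 0.55, with 10 rises and 1 fall. Camera called this list (adjusted p = 3.39e-06), but not with an estimated correlation (adjusted p = 0.231). Osteocyte genes had a median of 0.81, with 1 fall of 6, Fbln7 (−0.80, adjusted p = 0.0322), and 3 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.00237, and adjusted p = 0.0553 with an estimated correlation). Canonical Wnt targets had a median of 0.40, with Wisp1 (0.74, adjusted p = 0.0354) and Notum (5.05 ± 2.29 to 13.2 ± 4.63 FPKM, 1.23, adjusted p = 0.0418) rising and Wisp2 falling of 17. Adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 3.02e-06, and adjusted p = 0.0109 with an estimated correlation). The calls of Wisp1 and Notum each ended in 9 of the 12 fits with 1 library left out (highest adjusted p = 0.108 and 0.134). Smooth muscle and contractile genes fell in 6 of 10, and in 9 adjusted over the list alone, with Myl9 (−1.44, adjusted p = 0.000609) and Acta2 (−1.24, adjusted p = 0.00143). After quantile normalization, as with median-of-ratios scaling, 2 of the 10 fell. Their median was −0.71 (camera adjusted p = 3.02e-06, and adjusted p = 0.0109 with an estimated correlation). Tendon and ligament genes held 3 falls of 7, Aspn, Fmod (−0.99, adjusted p = 0.0192) and Tnc (−1.15, adjusted p = 0.0428). Their median was −0.99 (camera adjusted p = 0.00932, and adjusted p = 0.12 with an estimated correlation). BMP-SMAD targets held 0 calls of 21 (limma, median −0.05 with the camera direction up, adjusted p = 0.166).

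Mineralization and phosphate genes (median 0.20, 0 called of 11, camera adjusted p = 0.0391) and immediate early genes (median 0.17, 0 called of 15, adjusted p = 0.00907) were each called as a list by camera. They were not called with an estimated correlation (adjusted p = 0.604 for both) nor after quantile normalization (0.122 and 0.0763). Cholesterol synthesis genes had a median of −0.41, with Fdft1 and Fdps falling of 16, and 1 rising and 11 falling adjusted over the list alone (camera adjusted p = 0.00976, and adjusted p = 0.604 with an estimated correlation). Cytosolic ribosomal protein genes had a median of −0.69, with Rpsa falling of 23 (log2 −0.70, adjusted p = 0.0383) and 21 falling adjusted over the list alone (camera adjusted p = 5.78e-06, and adjusted p = 0.604 with an estimated correlation). Fibrillar and interstitial matrix genes held 3 falls of 25, Col3a1 (−1.62, adjusted p = 0.00238), P4ha3 (−0.93, adjusted p = 0.02) and Col12a1 (−1.36, adjusted p = 0.0282), and that list was not called (adjusted p = 0.96). BMP and TGF-β ligands and receptors held 3 falls of 23, the activin antagonist gene Fst (−1.44, adjusted p = 0.00575), Fstl1 and the coreceptor gene Tgfbr3 (adjusted p = 0.482 for the list, with the camera direction up and a median of −0.04). Wnt ligands, receptors and modulators held 1 rise, Lrp4, and 2 falls, Sfrp2 and Rspo2, of 26 (adjusted p = 0.96, with the camera direction up and a median of −0.18). Matrix proteases held 1 rise, Adamts12, and 2 falls, Mmp13 and Adamts1, of 14 (adjusted p = 0.482). Other falls in lists that were not called were Cxcl12 (−1.45), Postn (−1.15), Matn3 (−0.80), Lfng (−1.34) and Ifi27l2a (−1.66). All 26 cell cycle genes were lower (median −1.02, 0 called, but 26 without the first replicates). Camera gave adjusted p = 0.153, 1.13e-09 with the replicate block, 0.00312 after quantile normalization, and 0.862 with the estimated correlation of 0.985. The 16 ER stress genes had a median of 0.18 (camera adjusted p = 0.0541, 0.0163 with the replicate block, and 0.689 with an estimated correlation). After quantile normalization, falls numbered 1 each in the tendon, fibrillar matrix, BMP and TGF-β and matrix protease lists, and 0 in the osteocyte, cholesterol synthesis, ribosomal protein and Wnt ligand lists.

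Between these arms, limma called 506 genes, 74 higher and 432 lower, all without overlap, against 33.59% of all tested genes where chance gives 10%. The median tested gene was shifted by −0.19, and quantile normalization gave 135 rises and 126 falls, 196 of them shared with the 506. Centring itself sets this near-even split, so it cannot tell whether the excess of falls is real. The count was 1710 with the replicate block, 35 with only these arms in the fit, and 2512 from replicates 2 and 3 alone (620 rises and 1892 falls), which hold 475 of the 506. Left-out libraries moved it to 234 and 216 (Control replicates 2 and 3), 228 (RSPO2 replicate 2), 222, 65 and 60 (BMP2 replicates 1, 2 and 3) and 157 (BMP2+RSPO2 replicate 2). Of the 35 called genes of the naming rule, 8 were called without each library in turn, namely Prex1, Ptgfr, Ptx3, Specc1, Acta2, Myl9, Col3a1 and Fst, and the other 27 each lost the call in at least 1 such fit. Under each of the 3 scalings 18 of the 35 were called. Falling genes were enriched for extracellular region (59 of 429 where 17.6 were expected, adjusted p = 1.24e-13).

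**Figure D3:**
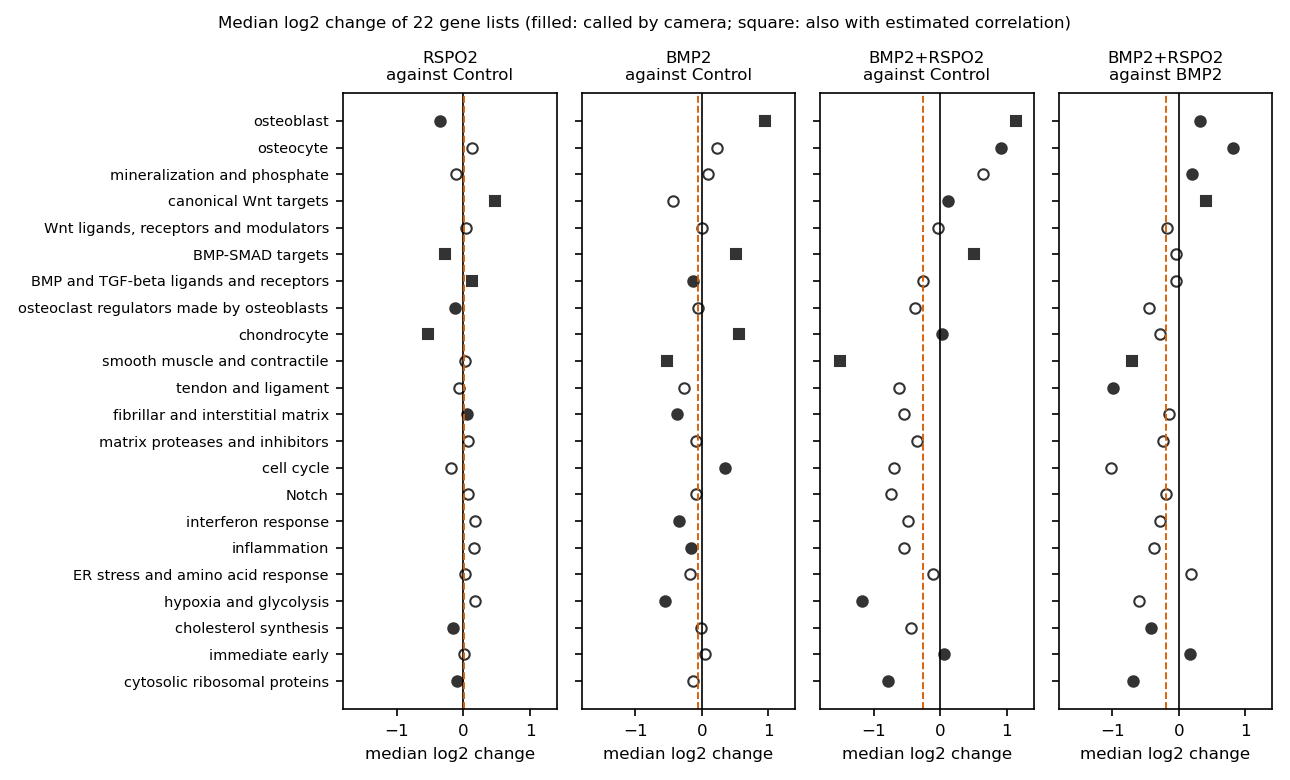
Points show the median log2 change of the tested members of 22 gene lists in RSPO2 against Control, BMP2 against Control, BMP2+RSPO2 against Control and BMP2+RSPO2 against BMP2, filled where camera called the list and square where the call also held with an estimated correlation, with a dashed line at the median of all tested genes. The osteoblast list lies at −0.35, 0.95, 1.13 and 0.32, and the smooth muscle list at −0.71 when RSPO2 is added to BMP2.

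Against RSPO2 alone, both proteins together raised osteoblast genes and lowered contractile genes. Ibsp rose from 308 ± 77.2 to 2610 ± 554 FPKM (log2 3.09, SE 0.26, adjusted p = 3.55e-05) and Alpl from 7.64 ± 1.90 to 31.9 ± 6.24 FPKM (1.93, SE 0.19, adjusted p = 0.000101). So did Sp7 (1.78, SE 0.28, adjusted p = 0.00159) and Runx2 (0.89, SE 0.15, adjusted p = 0.00228). Id1 (1.90, adjusted p = 0.000205), Smad6 (0.92, adjusted p = 0.00285), Dlx5 (1.22, adjusted p = 0.00399) and Tnfrsf11b (0.73, adjusted p = 0.015) rose, and Nkd2 (−2.49, SE 0.17, adjusted p = 9.75e-06) and Axin2 (−1.19, SE 0.25, adjusted p = 0.00651) fell. Dmp1 (5.21, SE 1.95, adjusted p = 0.0724), Lef1 (−0.49, 0.0784) and Znrf3 (0.16, 0.584) were not called. The largest rises were Slc36a2 (4.48), Cd200 (3.92), Col11a2 (3.83), the sodium-calcium exchanger Slc8a3 (3.42), Prex1 (3.22) and Sgms2 (3.18), and the largest falls Tnnc2 (−5.47), Aspn (−4.64), Gfra2 (−4.42), Igfbp2 (−4.32), Enpp2 (−4.28) and Apod (−3.53), with adjusted p from 3.39e-07 for Igfbp2 to 0.00104 for Col11a2.

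Of 17 osteoblast genes, 16 rose and Omd fell, also adjusted over the list alone. Their median was 1.78 (camera adjusted p = 2.82e-21, and adjusted p = 0.0122 with an estimated correlation). BMP-SMAD targets held 12 rises and 4 falls of 21 (median 0.55, camera adjusted p = 2.11e-10, and adjusted p = 0.00174 with an estimated correlation). Chondrocyte genes held 4 rises of 8, with Sox9 (0.71, adjusted p = 0.0154) among them (median 0.58, camera adjusted p = 9.02e-05, and adjusted p = 0.0122 with an estimated correlation). Smooth muscle and contractile genes held 9 falls of 10 (median −1.57, camera adjusted p = 2.49e-07, and adjusted p = 0.00689 with an estimated correlation). The calls of 6 more lists were lost with an estimated correlation, namely osteocyte (median 0.77, adjusted p = 0.022, then 0.108), mineralization and phosphate (0.26, 0.046, then 0.577) and fibrillar and interstitial matrix, with 4 rises and 15 falls of 25 (−0.90, 0.022, then 0.386). The others were hypoxia and glycolysis (−1.36, 0.00266, then 0.589), immediate early (0.02, 0.0294, then 0.655) and cytosolic ribosomal protein genes, with 13 falls of 23 (−0.69, 0.00251, then 0.669), of which 0 held under either quantile normalization or median-of-ratios scaling. After quantile normalization the osteocyte (adjusted p = 0.061), mineralization (0.178) and immediate early (0.233) lists were not called, and the tendon (0.0459), interferon response (0.00882) and inflammation (0.0275) lists, not called before it, were called as lower. Without that normalization and with an estimated correlation, adjusted p was 0.386 for each of the latter 3. Canonical Wnt targets held 4 rises and 6 falls of 17 and were not called as a list (median −0.67, adjusted p = 0.952). The count of genes was 3015, 499 higher and 2516 lower. Of these, 2979 do not overlap, against 42.34% of all tested genes where chance gives 10%. Of the 76 called genes of the naming rule, 66 were called without each library in turn and 67 under each scaling, and Sox9 lost its call in 1 such fit (adjusted p = 0.0613). The count was 1947 and 1847 without RSPO2 replicates 1 and 2, and quantile normalization gave 876 rises and 949 falls, against a median shift of −0.26.

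The interaction asks whether RSPO2 acted differently in the presence of BMP2. Nkd2 rose with RSPO2 alone, while with BMP2 and with both it was at 0.153 ± 0.157 and 0.307 ± 0.0802 FPKM (interaction log2 −1.53, SE 0.23, adjusted p = 0.0308). Igfbp2 rose with RSPO2 alone, while it was at 12.3 ± 2.85 FPKM with BMP2 and 5.91 ± 0.329 with both (−2.02, SE 0.22, adjusted p = 0.0165). Wisp2, a Wnt-induced secreted protein gene, was at 15.0 ± 7.01 FPKM in Control and 29.7 ± 10.4 with RSPO2, and fell when RSPO2 was added to BMP2 (−3.16, SE 0.47, adjusted p = 0.0308). Prex1 went the other way, at 0.783 ± 0.336 and 0.270 ± 0.151 FPKM without BMP2 and 1.75 ± 0.166 and 11.05 ± 3.04 with it (2.57, SE 0.30, adjusted p = 0.0165). Neurog2 was listed at 0 in the 6 libraries with BMP2, so no RSPO2 effect was measured there and no interaction is given for it. The other named genes were Clec2d (−1.71, adjusted p = 0.0242) and 4 more. These were Col3a1 (−1.61, adjusted p = 0.0384), the imprinted gene Mest (−1.61, adjusted p = 0.0373), Myl9 (−1.49, adjusted p = 0.0165) and Acta2 (−1.22, adjusted p = 0.0308). Of the panel, Ibsp had an interaction of 1.56 (SE 0.37, adjusted p = 0.125), Alpl of 0.83 (SE 0.27, 0.255) and Axin2 of −0.48 (SE 0.35, 0.558), and Nkd2 alone was called. Each of the 10 named calls, Neurog2 included, ended without at least 1 library, in 5 to 10 of the 12 fits, and of the 10 only Prex1 was called under each of quantile normalization, median-of-ratios and protein-coding scaling.

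Osteoblast genes as a group were lower with RSPO2 in the absence of BMP2 (median −0.35) and higher with it in the presence of BMP2 (median 0.32), calls that were both lost with an estimated correlation (adjusted p = 0.105 and 0.231). They had a median interaction of 0.79, 16 of 17 positive, 0 called over all genes tested and 1 rising adjusted over the list alone. Camera called this list (adjusted p = 1.2e-13, and adjusted p = 0.0566 with an estimated correlation). Smooth muscle and contractile genes fell with RSPO2 in the presence of BMP2 (median −0.71) and were not called without BMP2 (median 0.03). All 10 interactions were negative, with Myl9 and Acta2 called and 8 called adjusted over the list alone. The median interaction was −0.84 (camera adjusted p = 2.37e-07, and adjusted p = 0.0126 with an estimated correlation). BMP-SMAD targets were lower with RSPO2 in the absence of BMP2 (median −0.28) and not called in its presence (median −0.05), with a median interaction of 0.21 and 14 of 21 positive (camera adjusted p = 0.000515, and adjusted p = 0.0267 with an estimated correlation). Quantile normalization gave medians of 0.11 in its presence and 0.41 for the interaction, and median-of-ratios scaling 0.10 and 0.41. Another 6 lists were called by camera and lost the call with an estimated correlation. These were tendon and ligament (median −0.55, adjusted p = 0.0267, then 0.138), cytosolic ribosomal protein (−0.60, 0.00127, then 0.622), osteocyte (0.43, 0.0448, then 0.145), mineralization and phosphate (0.12, 0.0448, then 0.558), chondrocyte (0.28, 0.037, then 0.138) and immediate early genes (0.22, 0.037, then 0.622). Of these, the osteocyte (0.0873), mineralization (0.105), chondrocyte (0.105) and immediate early (0.165) lists also lost it after quantile normalization. The hypoxia and glycolysis list (median −0.84, adjusted p = 0.0739) was called after it (0.0155), and was at 0.727 with an estimated correlation. All 26 cell cycle genes had negative interactions (median −0.84, 0 called, camera adjusted p = 0.607, 1.40e-06 with the replicate block, and 0.892 with an estimated correlation), with 22 called from replicates 2 and 3 alone.

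For the interaction, limma called 34 genes, 1 higher (Prex1) and 33 lower, with a median shift of −0.21 over all tested genes, and quantile normalization gave 3 and 9, with 10 of the 12 among the 34. The count was 0 without Control replicate 2 or 3 or without BMP2 replicate 2 or 3, 13, 1 and 10 without RSPO2 replicates 1, 2 and 3, and 187, 16 and 5 without BMP2+RSPO2 replicates 1, 2 and 3. From replicates 2 and 3 alone it was 1109, which hold all 34. Across the tested genes, which are not independent replicates, the log2 effect of RSPO2 on BMP2-treated cells and its effect on untreated cells had a correlation of 0.168, with values from −0.0703 (without RSPO2 replicate 3) to 0.296 when 1 library was left out. The effects of BMP2 with and without RSPO2 correlated at 0.594 (0.473 to 0.638 when 1 library was left out).

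**Figure D4:**
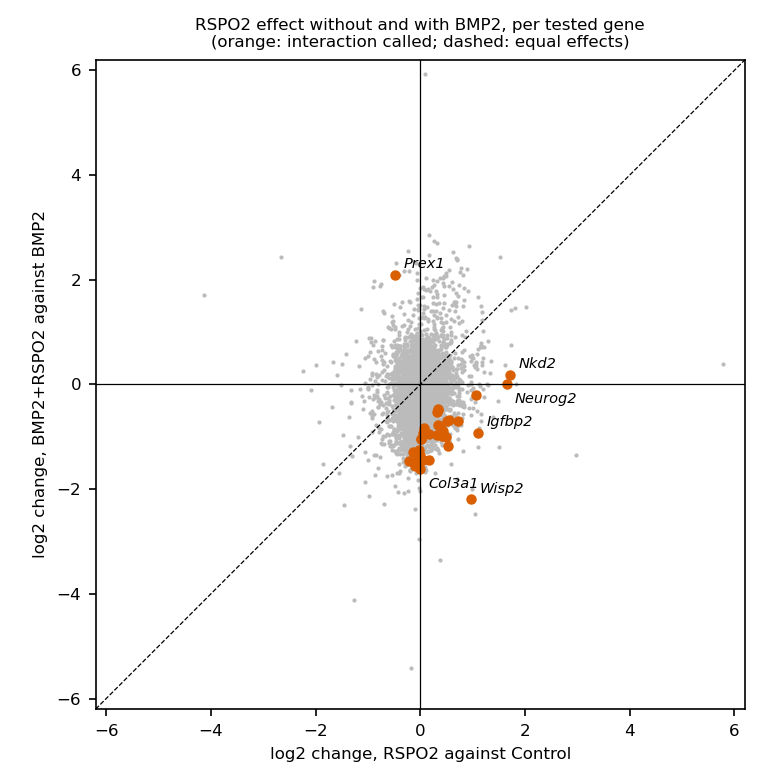
Each point is a tested gene, with the log2 change of RSPO2 against Control on the horizontal axis and of BMP2+RSPO2 against BMP2 on the vertical axis, the dashed line marks equal effects, and the 34 genes of the interaction are in orange. Nkd2 lies at 1.72 and 0.19 and Prex1 at −0.48 and 2.10, and r across genes is 0.168.

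The lists with fewer than 5 tested members held few changes. Of 2 adipocyte genes, Cebpa fell (log2 −1.17, adjusted p = 0.00117) and Scd1 rose (0.68, adjusted p = 0.0181) with both proteins against Control. Of 3 skeletal muscle genes, Tnnc2 is among the largest falls above, and Des and Tnnc1 were not called in any comparison. Of 1 endothelial gene, Flt1 was called against Control with both proteins (−1.38, adjusted p = 0.00271) but not with BMP2 (−0.99, adjusted p = 0.0704). The macrophage genes Cd68, Cd14, Fcer1g and Cd74 and the mitochondrial transcript mt-Nd6 were not called in any comparison by limma.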

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

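The comparison of the RSPO2 effect with and without BMP2 was fixed before the data were examined, while of the tests below on single libraries and on the direction of the changes only that for a mislabelled library was fixed before its result was seen.

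Genes and lists are given here where RSPO2 effects with and without BMP2 were called different. This gave 34 genes, 3 with median-of-ratios scaling, and 0 without replicate 2 or 3 of Control or BMP2. The log2 difference in effect was −1.53 for Nkd2 (SE 0.23, adjusted p = 0.0308) and 2.57 for Prex1 (SE 0.30, 0.0165). It was −3.16 for Wisp2 (SE 0.47, 0.0308), −2.02 for Igfbp2 (SE 0.22, 0.0165) and −1.71 for Clec2d (SE 0.23, 0.0242). It was −1.61 for Col3a1 (SE 0.27, 0.0384), −1.61 for Mest (SE 0.26, 0.0373), −1.49 for Myl9 (SE 0.17, 0.0165) and −1.22 for Acta2 (SE 0.18, 0.0308). None is given for Neurog2, listed at 0 with BMP2. With 3 libraries per arm, single libraries of these genes were not tested as outliers.

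By camera, the effect on the list differed for osteoblast genes (adjusted p = 1.2e-13, and adjusted p = 0.0566 with an estimated correlation), BMP-SMAD targets (0.000515, and 0.0267), smooth muscle and contractile genes (2.37e-07, and 0.0126), tendon and ligament genes (0.0267, and 0.138), chondrocyte genes (0.037, and 0.138), osteocyte genes (0.0448, and 0.145), mineralization and phosphate genes (0.0448, and 0.558), immediate early genes (0.037, and 0.622) and cytosolic ribosomal protein genes (0.00127, and 0.622).

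When the libraries were regrouped, the true grouping gave the most genes in each comparison of a pair of arms, 1 of 10 possible splits each, and the next highest split gave 2 genes for RSPO2 against Control, 1 for BMP2 against Control, 2 for BMP2+RSPO2 against Control, 1 for BMP2+RSPO2 against BMP2 and 1 for BMP2+RSPO2 against RSPO2. With 10 splits no share under 0.05 can be reached, so whether chance alone could give these counts stays open. For the interaction, 4 of 100 splits gave at least 34 genes, the highest other split 505, and its cause was not tested.

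BMP2+RSPO2 replicate 1 lies apart from replicates 2 and 3 of its arm. Its histone genes were higher by a median log2 difference of 3.87, the values that RNA without poly(A) tails in the library would give. A mislabelled library is argued against by its correlation of 0.574 with its own arm, against 0.0557 at most with another arm. A single scaling factor would leave the spread across genes as it is. Over 4273 protein-coding genes at 10 FPKM or more, histone genes left out, the median absolute deviation of the log2 difference from replicates 2 and 3 was 0.463 in this library and 0.336 at most in the other first replicates, which argues against a single factor as the only cause. Whether such a factor had a part was not tested.

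Cell cycle genes were higher in replicate 1 of all 4 arms. The largest shift of the median gene in a first replicate was −0.13 on the log2 scale, which argues against scaling between libraries. The deviations of the first replicates correlate by 0.161 or more, as a separate batch of cultures or libraries would give. Those of the second replicates do too (0.246 to 0.408), which a replicate 1 shift alone can give, as deviations cancel within an arm. A separate batch remains open. So do less mature cultures, since the osteoblast list median was lower in the first replicate of all arms but by only −0.0214 with BMP2.

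Most calls in the comparisons of BMP2+RSPO2 are falls. After quantile normalization 50.8% of the calls against Control were falls, but centring itself sets this value, so scaling of FPKM by a changed make-up of the RNA remains open. Without BMP2+RSPO2 replicate 1 the share was 77.88%, which argues against that library as the only source.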

How the results depend on the processing

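Replicates 2 and 3 alone, the batch term, the library weights and the protein-coding scaling were chosen after seeing the results.

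The table has 1 value per gene, so no setting by transcript was run, a fit of only the arms compared does not apply to the interaction, and the filter at 5 FPKM drops some named genes. An arm with 1 library left out has 2 and takes its spread from the other arms. Directions of named genes held in nearly all settings, and what moved most was how many genes passed. The cause was not tested for results that changed. The robust variance model changed none of 289 named results.

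The count for RSPO2 against Control was 9, and 0 with a pseudocount of 0.1, 0 with a filter at 5 FPKM, 5 after quantile normalization, 26 with the replicate block, 0 with only these arms, 195 from replicates 2 and 3, 39 with a batch term and 329 with library weights. With 1 library left out it was 0 to 21. For BMP2 against Control it was 175, and 329 with the replicate block, 963 from replicates 2 and 3, 453 with a batch term, 1677 with weights, 100 with an absolute log2 change of at least 1, and 65 to 403 with 1 library left out. For BMP2+RSPO2 against Control it was 2656, and 1697 with median-of-ratios scaling, 1626 after quantile normalization, 1694 with protein-coding scaling, and 1172 with only these arms. It was 3897 with the replicate block, 3994 from replicates 2 and 3, 4397 with a batch term, 5401 with weights, and 645 with a log2 change of at least 1. It was 1595 to 2758 with 1 library left out.

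For BMP2+RSPO2 against BMP2 it was 506, and 306 without the filter, 279 with median-of-ratios scaling, 261 after quantile normalization, 299 with protein-coding scaling, and 1710 with the replicate block. It was 35 with only these arms, 2512 from replicates 2 and 3, 2284 with a batch term, 4491 with weights, and 112 with a log2 change of at least 1. It was 60 to 709 with 1 library left out. For BMP2+RSPO2 against RSPO2 it was 3015, and 1831, 1825 and 1883 under these scalings, 4159 with the replicate block, 1237 with only these arms, 4589 with a batch term, 5933 with weights, and 790 with a log2 change of at least 1. It was 1847 to 3058 with 1 library left out. For the interaction it was 34, and 3, 12 and 8 under these scalings, 91 with the replicate block, 1109 from replicates 2 and 3, 297 with a batch term, 2225 with weights, and 0 to 187 with 1 library left out.

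Of the lists, 9 were called for RSPO2 against Control (4 with an estimated correlation, 4 with fry, 7 to 12 with 1 library left out), 10 for BMP2 against Control (4 with an estimated correlation, 5 to 11 left out) and 9 for BMP2+RSPO2 against Control (3, 16 with fry, 8 to 11). It was 9 for BMP2+RSPO2 against BMP2 (2, 5 to 11), 10 for BMP2+RSPO2 against RSPO2 (4, 16 with fry, 8 to 12) and 9 for the interaction (2, 4 to 12). The correlation of the RSPO2 effects with and without BMP2 was 0.168, and −0.0703 to 0.296 with 1 library left out.

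None of the genes whose sign turned was called, except Pdia4. With 1 library left out, the log2 change of Alpl for RSPO2 against Control went from −0.30 to 0.00494 and that of Dmp1 from −2.36 to 0.42. That of Znrf3 went from −0.00819 to 0.13 for BMP2 against Control, from −0.000251 to 0.46 for BMP2+RSPO2 against BMP2 (−0.0251 from replicates 2 and 3), from −0.0873 to 0.37 for BMP2+RSPO2 against RSPO2 (−0.0799 from replicates 2 and 3, −0.0402 with weights) and from −0.13 to 0.33 for the interaction (−0.23 and −0.18). Lef1 went from −0.0331 to 0.31 for BMP2+RSPO2 against Control (−0.0262 from replicates 2 and 3, −0.0427 with weights), and from −0.27 to 0.0743 for the interaction (0.0447 with a pseudocount of 0.1, and 0.11, 0.13 and 0.10 under the scalings). For BMP2+RSPO2 against BMP2, from replicates 2 and 3 and with weights, Runx2 was at −0.00655 and −0.0174 and Id1 at −0.0181 and −0.0328. Pdia4 for BMP2+RSPO2 against Control was at 0.0214 after quantile normalization. Smad6 for the interaction was at 0.01997 with median-of-ratios scaling, 0.0202 from replicates 2 and 3, 0.0289 with weights and 0.0104 with protein-coding scaling.

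Deviations from the arm mean correlated between same-numbered libraries by over 0.1 in 16 of 18 pairs (−0.125 to 0.631), and 10 of 12 libraries correlate best with their own number. Beyond the values given with the results, the replicate block changed no other call of a panel gene or list in the paired comparisons or the interaction.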

Other observations

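The tests in this part were chosen after the results were seen, except for the correlations of effects.

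Most genes called with BMP2 had a log2 change of the opposite sign with RSPO2 alone, although only 9 genes were called for RSPO2. Of the 116 genes that fell with BMP2, 94 were higher with RSPO2 alone than in Control, with a median log2 change of 0.29. Among them were Enpp2 (30.5 ± 18.1 FPKM in Control, 95.2 ± 21.6 with RSPO2, 2.10 ± 1.40 with BMP2), Tnnc2 (31.1 ± 10.9, 66.7 ± 15.7 and 2.50 ± 0.681), Fbn1 (9.10 ± 1.41, 17.8 ± 1.15 and 1.06 ± 0.104), Sfrp2 (61.2 ± 5.04, 102 ± 16.6 and 25.2 ± 1.79) and the BMP antagonist gene Grem1 (20.4 ± 6.24, 42.6 ± 0.930 and 4.37 ± 1.50). Of the 59 genes that rose with BMP2, 50 were lower with RSPO2 alone (median −0.17). When RSPO2 was added to BMP2, 90 of the 116 were lower again (median −0.38, against −0.19 for all tested genes), and 33 of the 59 were higher (median 0.08). From replicates 2 and 3 alone, 371 of 530 falls with BMP2 were higher with RSPO2 alone, and 343 of 433 rises were lower. In those libraries 170 of the 433 were higher with RSPO2 on BMP2 (median −0.21, against −0.109 for all tested genes), unlike the 33 of 59 above. After quantile normalization the numbers were 77 of 95 and 61 of 75, and 60 of the 95 were lower again on BMP2.

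Both effects share the Control libraries, which by itself makes them correlate. In 100 simulations of independent libraries without any effect, the correlation across genes was 0.501 on average and 0.42 at the lowest, against −0.0848 in the data, and 66.6% of genes had the same sign, against 47.9%. Same-numbered libraries are not independent here, and what they share cancels in part. From the deviations of same-numbered libraries, the correlation expected without any effect is 0.396 and the covariance 0.0178, against −0.00719 in the data. These expected values rest on 3 libraries per arm and have no spread.

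From replicates 2 and 3 alone, genes that rose with RSPO2 were enriched for negative regulation of canonical Wnt signalling (9 of 64 genes where 0.801 were expected, adjusted p = 4.05e-05), and genes that fell for ossification (7 of 51 where 0.333 were expected, adjusted p = 3.12e-05). In the same libraries, genes that rose with BMP2 were enriched for cell cycle (60 of 406 where 17.1 were expected, adjusted p = 6.92e-15), and genes that fell when RSPO2 was added to BMP2 were enriched for that term too (143 of 406 where 73.2 were expected, adjusted p = 1.91e-14). The enrichment test treats genes as independent. Camera with an estimated correlation, run on these libraries, called none of the related lists. Its adjusted p was 0.0713 and 0.0969 for cell cycle genes in these BMP2 comparisons. For RSPO2 against Control it was 0.112 for canonical Wnt targets and 0.35 for osteoblast genes.

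Mmp13 was at 4.29, 38.1 and 40.3 FPKM in BMP2 replicates 1, 2 and 3, and Dmp1 at 0.160, 0.190, 4.25 and 21.4 FPKM in replicate 1 of Control, RSPO2, BMP2 and BMP2+RSPO2, below both other replicates of the arm in each case. Bglap2 was at 57.9 FPKM in BMP2+RSPO2 replicate 1, against an arm mean of 912 ± 741 FPKM. Ddr2 was at 45.5 FPKM in Control replicate 2, against an arm mean of 22.9 ± 19.6 FPKM.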
